A study of Shewanella oneidensis with 8 samples.

How the data were processed

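RNA from electrode-associated cells was measured on 8 arrays of 1 colour, 4 per group, and each array is 1 biological replicate, per the labels. Total RNA was extracted with Trizol, and Cy3-labelled cRNA was made from 25 ng of it, per the labels. The scanner files hold intensity values per spot: the processed signal is a background-subtracted intensity that the authors deposited as Agilent Feature Extraction wrote it, with no scaling between arrays. The file headers name Feature Extraction 11.5.1.1, while the submitters' processing notes name version 8.1 and limma 3.36.2; which steps limma was used for is not given in the sources used here. The authors' deposited series table holds log2 values. Its columns have medians of 8.99 or 9.00 and follow the order of the median signal less the median local background on each array (Spearman 1), so its scale is log2 and its direction that of the signal; how the table was made is not given in the sources used here.

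Probe values were log2 of the processed signal minus each array's 75th percentile over 13379 non-control probes. Control spots and 7 outlier spots were left out, and 0 spots were saturated. A gene's value was the mean over its probes, 3 probes for 4186 genes, 2 for 238 and 1 for 345. Among 2604 called genes with at least 2 probes, 181 had probes that differed in sign. Genes needed at least 1 probe well above background on at least 4 of the 8 arrays, which kept 4747 of 4769. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, flow minus non-flow, with Benjamini-Hochberg adjustment over the genes tested, and all gene-level adjusted p-values are limma's. The median standard error was 0.149 log2, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

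The fit was tested on simulated data with 200 changed genes among 4747: 79% of 2-fold and 20% of 1.4-fold changes were recovered, with 5 false calls (4.8% of calls) and 0 of wrong sign. The simulation had independent noise, no trend on mean signal and far fewer changed genes than the 2812 called in the data. These shares therefore do not carry over to the data.

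Locus tags are those of the array. Of these, 4137 matched the gene table of assembly ASM14616v2, and 1220 had a symbol there; other genes are given by locus tag. The array's build is not given in the sources used here, so no coordinates are printed.

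The groups, tests, settings to be tried, gene lists and the rule for named genes were fixed before the data were examined. The rule named the 10 largest rises and 10 largest falls among called genes with no overlap between groups and well above background on all arrays of the brighter group; of each list up to 4 called members of largest change, or up to 2 tested members where fewer than 2 were called; and always the mtr-omc cluster, cymA, SO_3096 and called sigma factor genes. Some lists had been defined by product text, which the array and the gene table do not carry. Before any test these lists were rebuilt from locus tags and symbols, and 5 (cyclic di-GMP enzymes, TonB-dependent receptors, transposases, multidrug efflux and cold shock) were dropped, which left 33. They were extracellular electron transfer, other anaerobic respiratory reductases, terminal oxidases and bc1 complex, cytochrome c maturation, c-type cytochromes, heme biosynthesis, hydrogenases and formate dehydrogenases, lactate and pyruvate use, TCA cycle, NADH dehydrogenases, ATP synthase, ribosomal proteins, aminoacyl-tRNA synthetases, flagellum, chemotaxis, type IV and MSHA pili, biofilm matrix, iron acquisition, heat shock and proteases, oxidative stress defence, sigma and anti-sigma factors, the prophages LambdaSo, MuSo1 and MuSo2, amino acid biosynthesis, purine and pyrimidine biosynthesis, sulfate assimilation, phosphate starvation, SOS response, fatty acid beta-oxidation, fatty acid biosynthesis, type II secretion and glycogen metabolism. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, and adjusted over the lists.

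Settings tried were quantile, median, cyclic loess and no scaling, normexp (offset 50) before 75th percentile or quantile scaling, the authors' series table, a signal floor, other filters on dim probes, the brightest probe or median of probes, eBayes with trend and robust options, no overlap between groups, a replicate block, and each array left out in turn. Normexp used median spot and median background signals, since the files hold no mean spot signal. Leaving out saturated spots was void. Slide as a block could not be fitted, because each slide held 1 group. The removal of the trend on mean signal was added after seeing the data.

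A gene not well above background on any array of a group has a bound there. This held for 3 genes, all in the non-flow group and chosen after their values were seen: SO_0759 was at least 2.50-fold, SO_2729 at least 2.98-fold and SO_3989 at least 2.16-fold higher with flow (limma adjusted p = 1.71e-06, 5.04e-06 and 0.000613). The bound sets the mean of the brighter group against the mean, over the dim arrays, of the higher of the gene's own value and the lowest signal well above background on that array.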

Results

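Transcripts of Shewanella oneidensis MR-1, a bacterium that passes respiratory electrons to electrodes, were measured in cells taken from the working electrode of an electrochemical flow cell. The cells carried a construct named AFP in the labels and were otherwise wild type. The electrode stood at 0.2 V against the standard hydrogen electrode, and cells were given about 1 h to attach. In the flow group medium then passed at 5.5 mm per min for 48 h, and the non-flow group was kept without flow for 78 h, so the groups differed in cultivation time as well as in flow. Each group had 4 biological replicates, per the labels, with 1 array each. Of the non-control probes, 98.2% to 99.7% per array were well above background. The comparison asks which genes differ between electrode-associated cells with and without flow of medium, and the study's title names an extracytoplasmic function sigma factor as its subject.

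The flow and non-flow cells differed in a large share of their genes. Of 4747 genes tested, 2812 differed by limma at an adjusted p under 0.05, 1705 of them higher and 1107 lower with flow. A change of at least 2-fold was found for 955 genes, 690 higher and 265 lower (72.3% higher); this share was 59.2% (478 and 330) with quantile normalization, 58.0% (553 and 400) with median scaling, 60.7% (338 and 219) with normexp and quantile, 58.7% (445 and 313) with the authors' series values, 81.9% (830 and 184) with no scaling and 77.7% (851 and 244) with the brightest probe of a gene. Values of the groups did not overlap for 2581 genes, 54.4% of those tested, where chance gives 2.86%. Gene values correlated across genes at r between 0.974 and 0.992 within the non-flow group, between 0.981 and 0.989 within the flow group and between 0.901 and 0.922 across groups. The first principal component held 79.8% of the variance and parted the groups. The median gene was 0.13 log2 higher with flow, and the share of called genes that were higher depended on the scaling. It was 60.6% as reported, 42.7% (1163 higher, 1560 lower) with quantile normalization, 47.4% (1334 and 1479) with median scaling, 77.1% (1079 and 320) with no scaling, 50.4% (1344 and 1322) with cyclic loess, 44.0% (1189 and 1511) with normexp and quantile, 43.2% (1198 and 1576) with the authors' series values, and 50.5% (1305 and 1280) with the trend on mean signal removed, a setting chosen after seeing the data. All flow arrays lay on 1 slide and all non-flow arrays on another, scanned separately, so slide and condition cannot be told apart.

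SO_3096, an extracytoplasmic function sigma factor gene fixed for description ahead of the data, was 11.3-fold higher with flow (log2 difference 3.50 ± 0.14 SE, limma adjusted p = 1.85e-08), with means of 3.98 ± 0.06 (SD, n = 4) in flow and 0.48 ± 0.27 (SD, n = 4) in non-flow cells on the scaled log2 scale. Of the 9 sigma and anti-sigma factor genes tested, 1 rose, 3 fell and 5 did not pass the test, also when adjusted over the list alone. The 3 that fell were flgM, for the anti-sigma factor of flagellar genes (−1.16), rpoH, for the heat shock sigma factor (−0.60), and rpoD, for the main sigma factor (−0.50). rpoE, for another extracytoplasmic function sigma factor and named after its value was seen, had a log2 difference of 0.33 (adjusted p = 0.0608). The list as a whole did not shift by camera (adjusted p = 0.674).

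The strongest rises exceeded that of SO_3096. SO_2009 was 83.9-fold higher with flow (log2 6.39 ± 0.19 SE, limma adjusted p = 2.10e-09), and its neighbour SO_2008 75.8-fold. The pair msrP and msrQ, which encode a periplasmic methionine sulfoxide reductase and its membrane partner, rose 33.5-fold and 56.3-fold. SO_1773 rose 62.8-fold, SO_3098, close to SO_3096 by locus tag, 52.4-fold, SO_1381 42.2-fold, SO_1837 36.4-fold, SO_1838 29.8-fold and SO_0525 25.5-fold. The probes of SO_0525 ran from 2.38 to 6.02 log2, so the size of its rise is uncertain.

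**Figure D1:**
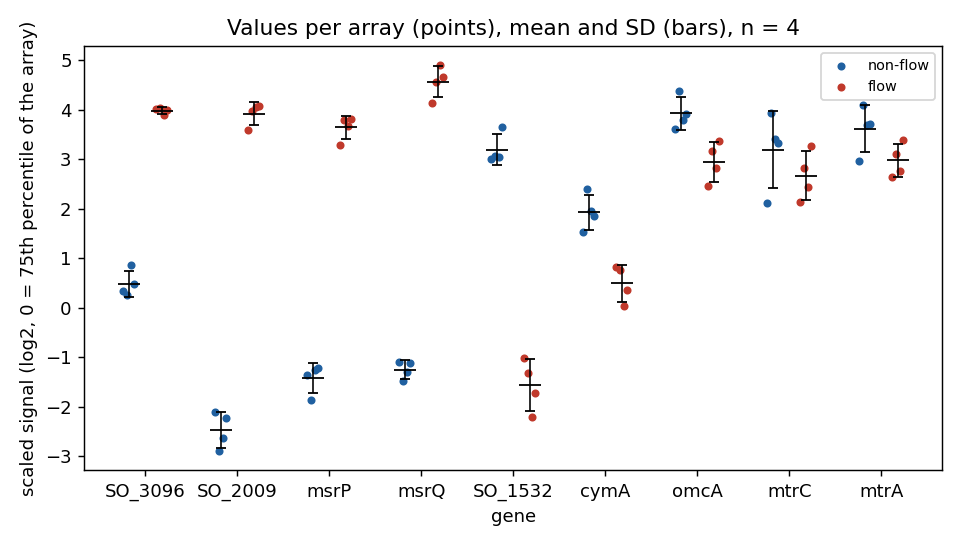
Scaled log2 signal (vertical axis) of 9 genes in each array, with non-flow replicates in blue and flow replicates in red, and bars for the mean and SD of 4 arrays. SO_3096, SO_2009, msrP and msrQ are higher in all flow arrays, SO_1532 and cymA are lower, and the groups overlap for mtrC and mtrA through non-flow replicate 1 alone.

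The largest fall was that of SO_1532, 27.0-fold lower with flow (log2 −4.76 ± 0.25 SE, limma adjusted p = 1.51e-07). SO_0458 was 9.54-fold lower, SO_1258 7.41-fold, SO_3342 7.01-fold, SO_1047 5.98-fold, SO_1337 5.72-fold, SO_1572 5.68-fold, SO_1813 5.63-fold, SO_1048 5.07-fold and SO_4716 4.88-fold. The reference table gave no symbol for these 10 genes. SO_0458 had 1 probe, so agreement between probes could not be checked for it.

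Of 10 genes of extracellular electron transfer 6 fell, 2 rose and 2 did not pass the test, over all genes and adjusted over the list alone, and the camera test did not pass (adjusted p = 0.0913). The list's median of −0.66 lay at percentile 6.06 of 10000 random lists matched on mean signal, a comparison chosen after the dependence on signal was seen (central 95% from −0.78 to 0.49). cymA, for the inner-membrane quinol-oxidizing cytochrome, fell by 1.44 ± 0.22 SE on the log2 scale (limma adjusted p = 0.000229), fccA, for fumarate reductase, by 1.26, omcA, for an outer-membrane cytochrome, by 0.97, SO_1776 by 0.81 and mtrA by 0.64. The outer-membrane cytochrome gene mtrC had a log2 difference of −0.52 (adjusted p = 0.230) and mtrF one of 0.34 (adjusted p = 0.101). Both rested on non-flow replicate 1: without it mtrC was at −0.89 (adjusted p = 0.0114) and mtrF at 0.17 (adjusted p = 0.236). That array had the lowest mean correlation with its own group (0.979) and a score of 23.3 on the second principal component. SO_1782 rose by 1.03 and SO_1781 by 0.44, but SO_1781 was lower with quantile normalization (−0.06) and cyclic loess (−0.01). With cyclic loess the calls of SO_1776 (adjusted p = 0.0511), mtrA (0.487) and SO_1782 (0.0553) ended. That of mtrA also ended with quantile normalization (0.128), no scaling (0.233), normexp and quantile (0.0795), the brightest probe (0.427), the median of the probes (0.175) and most single arrays left out (0.0522 to 0.104), and that of SO_1776 with no scaling (0.102). That of SO_1782 ended with quantile normalization (0.48, adjusted p = 0.0534), normexp and quantile (0.22, 0.071) and the median of the probes (0.28, 0.274). That of SO_1781 ended also with median scaling (0.132), no scaling (0.21), normexp and quantile (0.391), the authors' series values (0.571), the brightest probe (0.0863) and 4 single arrays left out (0.052 to 0.0734). With the trend on mean signal removed omcA was at −0.46 (0.0944), SO_1776 at −0.32 (0.131), mtrA at −0.15 (0.624), SO_1781 at −0.10 (0.618) and SO_1782 at 0.35 (0.135), none of them called.

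In other respiratory lists changes went both ways, and none shifted by camera. Among 20 other anaerobic reductase genes, 2 rose and 6 fell, with the nitrite reductase gene nrfA at −1.79, SO_4061 at −1.90, phsA at −1.69 and nrfD at −1.53 (camera adjusted p = 0.0704). Among 13 genes of terminal oxidases and the bc1 complex, 5 rose and 3 fell. The oxidase genes coxB (1.47) and ctaD (1.40) rose. Among 44 c-type cytochrome genes 12 rose and 14 fell, and among 14 heme biosynthesis genes 5 rose and 1 fell (4 and 1 adjusted over the list alone), with hemF at 1.24. Cytochrome c maturation had 3 rises and 3 falls in 14 genes, of which SO_0696 (4.47, 22.1-fold) was by far the largest. Among 28 hydrogenase and formate dehydrogenase genes 8 rose and 4 fell (7 and 4 over the list alone), with fdnG at 2.74 and SO_4509 at −1.98. NADH dehydrogenases had 5 rises and 1 fall in 26 genes (3 and 1 over the list alone).

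Of the prophages, LambdaSo had 42 higher and 3 lower of 75 genes (median 0.83), MuSo1 28 and 5 of 41 (median 1.12; 29 and 5 adjusted over the list alone) and MuSo2 44 and 5 of 53 (median 1.29). SO_2657 of MuSo2 rose 23.3-fold, SO_0643 of MuSo1 25.3-fold and SO_2999 of LambdaSo 7.92-fold. No probe of SO_0643 was well above background on more than 3 of the 4 non-flow arrays. Its probes ran from 3.16 to 5.94 log2, so the size of its rise is uncertain. The camera adjusted p was 4.45e-05, 0.00138 and 7.32e-08 in that order. With an estimated correlation none passed: adjusted p = 0.721 with an estimated correlation for LambdaSo and MuSo2, and adjusted p = 0.795 with an estimated correlation for MuSo1. Genes of the dimmest quintile by mean signal were higher by a median of 0.57. That quintile holds 31 of the 41 MuSo1 genes, 27 of the 53 of MuSo2 and 25 of the 75 of LambdaSo. The MuSo1 call ended with normexp before 75th percentile scaling (camera adjusted p = 0.146).

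**Figure D2:**
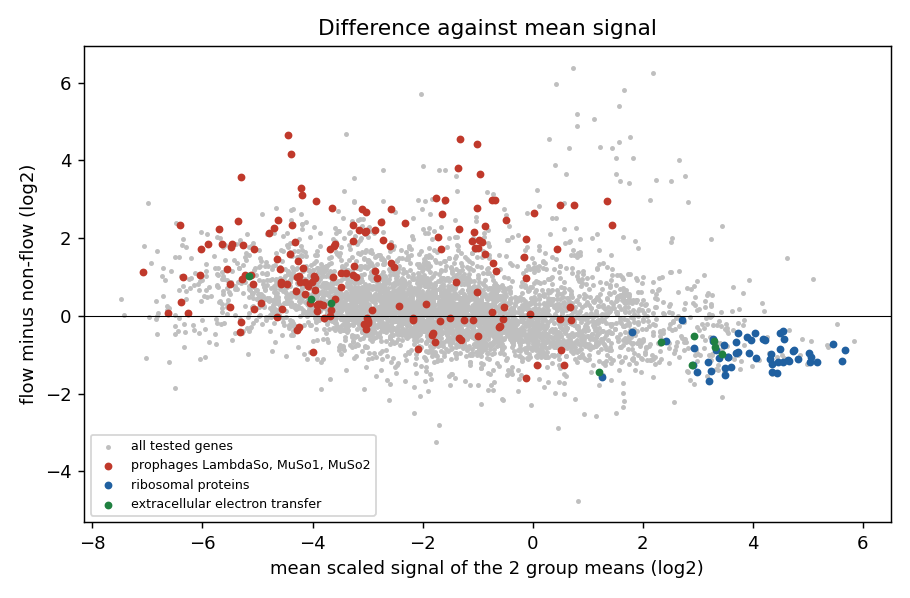
Log2 difference, flow minus non-flow (vertical axis), against the mean of the group means of scaled log2 signal (horizontal axis), 1 point per tested gene. Prophage genes are red, ribosomal protein genes blue and extracellular electron transfer genes green; the dimmest quintile of genes has a median of 0.57 and the brightest a median of −0.25.

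The flagellum list rose as well, with 30 of 50 genes higher and 6 lower (31 and 7 adjusted over the list alone; median 0.71, camera adjusted p = 0.0151, adjusted p = 0.841 with an estimated correlation). SO_3242 rose by 2.53 and flgK, for a hook-associated protein, by 2.31, while flgM fell. Of 14 chemotaxis genes 7 rose and 2 fell, with SO_2121 at 1.23 (camera adjusted p = 0.391). The flagellum median lay at percentile 100 of random lists matched on mean signal and that of chemotaxis at 70.8. The random lists draw genes singly, while the estimated correlation between flagellum members was 0.445, so its percentile does not measure chance.

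Ribosomal protein genes fell almost without exception: 53 of 54 were lower and rplS, named after its value was seen, had −0.11 (median −0.98, camera adjusted p = 4.25e-19, adjusted p = 0.721 with an estimated correlation). rpsI fell by 1.67 ± 0.21 SE. Of 13 heat shock and protease genes 10 fell and none rose (median −0.86, camera adjusted p = 0.000149, adjusted p = 0.721 with an estimated correlation), with the chaperone genes dnaK at −1.78 and groL at −1.25. Of 9 ATP synthase genes 8 fell, with SO_4746 at −1.39 and atpD at −1.26 (median −0.82, camera adjusted p = 0.000149, adjusted p = 0.721 with an estimated correlation). Of 20 aminoacyl-tRNA synthetase genes 9 fell and 1 rose, with glyQ at −0.80 (median −0.30, camera adjusted p = 0.00465, adjusted p = 0.795 with an estimated correlation). Of 32 genes for type IV and MSHA pili 9 fell and 3 rose (9 and 2 over the list alone), with pilV at −1.34 (median −0.18, camera adjusted p = 0.0315, adjusted p = 0.795 with an estimated correlation). All 54 ribosomal protein genes lie in the brightest quintile, which had a median of −0.25. Among random lists matched on mean signal the ribosomal median lay at percentile 0 (median of the random lists −0.58) and that of heat shock at 0.04 (−0.20). The falls of ATP synthase (percentile 14.7, random lists −0.56), aminoacyl-tRNA synthetases (27.6, −0.19) and pili (16.8, −0.05) lay inside the central 95% of these lists. The random lists were drawn from all tested genes, the ribosomal protein genes and the list's own members included. They therefore do not show that other genes of the same signal fall as much. Genes were also drawn singly, while the estimated correlation between members was 0.581 for ribosomal proteins and 0.365 for heat shock. These percentiles therefore do not measure chance. The calls for aminoacyl-tRNA synthetases and pili ended with quantile normalization (adjusted p = 0.0917 and 0.0899), with no scaling (0.0543 and 0.0563) and with cyclic loess (0.199 and 0.152), and that for pili also with normexp before scaling (0.0616), normexp and quantile (0.0847), the authors' series values (0.0769), non-flow replicate 3 left out (0.0501) and flow replicate 2 left out (0.0527).

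**Figure D3:**
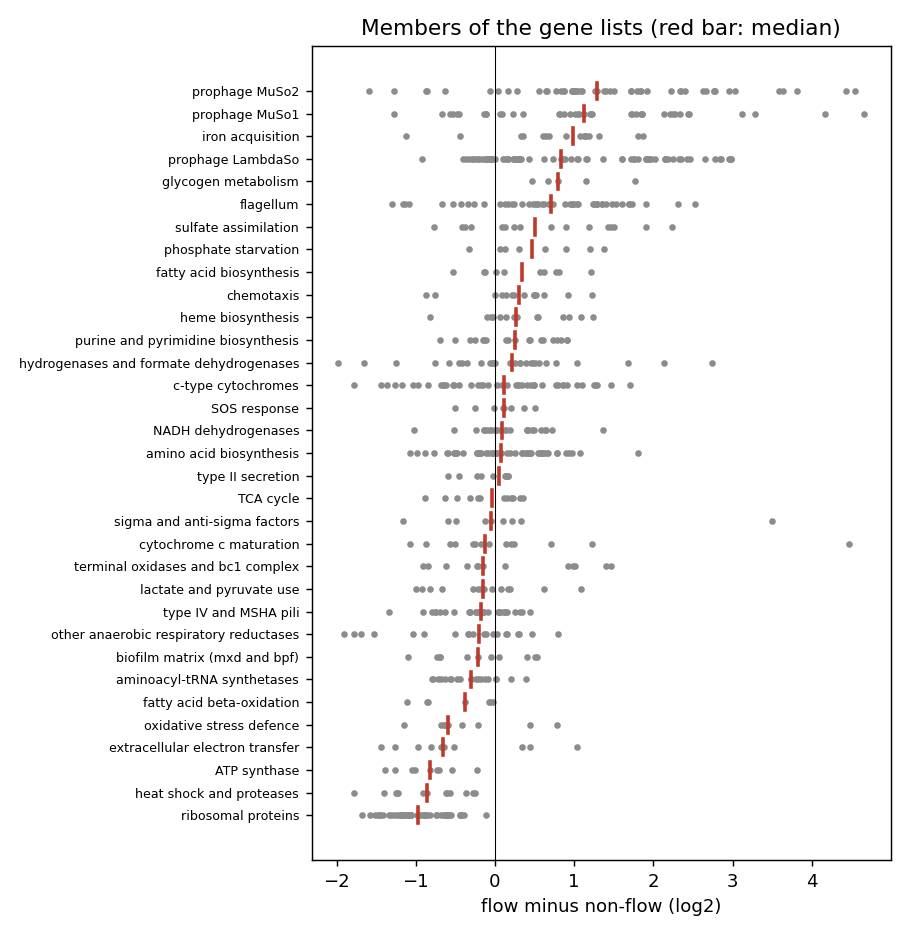
Log2 difference, flow minus non-flow (horizontal axis), of each tested member of the 33 gene lists (grey points), with the median of each list as a red bar. The medians run from −0.98 for ribosomal proteins to 1.29 for prophage MuSo2.

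The remaining lists did not shift by camera. Iron acquisition had 11 rises and 2 falls in 16 genes, with SO_3669 at 1.86 and hutX at 1.80 (adjusted p = 0.0758); its median of 0.99 lay at percentile 99.94 of random lists matched on mean signal (central 95% up to 0.66). The iron acquisition percentile does not measure chance, since the random lists draw genes singly and the estimated correlation between members was 0.346. Glycogen metabolism had 4 rises in 5 genes (5 adjusted over the list alone), with SO_1496 at 1.77 and glgC at 1.14 (adjusted p = 0.0838). Sulfate assimilation had 8 rises and 4 falls in 16 genes, with the transporter genes cysW at 2.24 and cysT at 1.91. Phosphate starvation had 4 rises and 1 fall in 8 genes (5 and 1 over the list alone), with pstC at 1.20. Oxidative stress defence had 4 falls in 9 genes, with sodB, for superoxide dismutase, at −1.15; katB, ahpC and dpsA fell by 0.65, 0.64 and 0.59 but were higher with cyclic loess (0.01, 0.13 and 0.05). Biofilm matrix genes had 3 rises and 5 falls in 11, with SO_4317 at −1.10. Amino acid biosynthesis had 19 rises and 7 falls in 57 genes, with lysC at 1.80, and purine and pyrimidine biosynthesis 9 and 2 in 19, with purN at 0.91. Fatty acid biosynthesis had 5 rises and 1 fall in 10 genes, with fabA at 1.21, and fatty acid beta-oxidation 3 falls in 7, with fadI at −1.11. The lactate and pyruvate list had 1 rise and 4 falls in 14 genes, with SO_1519 at −0.92, and the TCA cycle 1 rise and 3 falls in 12 (0 and 3 over the list alone), with mdh at −0.88. The SOS list had 2 rises and 1 fall in 8 genes, with ruvB at 0.51, and type II secretion 2 falls in 10 (1 over the list alone), with gspG at −0.46. For terminal oxidases, cytochrome c maturation, c-type cytochromes, hydrogenases, sigma factors, SOS and type II secretion the median, the mean and the direction of the camera test differed in sign. Lists with no second count had the same count adjusted over the list alone. With an estimated correlation 0 of the 33 lists passed. By camera at the preset correlation, 23 of the 35 ways to split the 8 arrays 4 against 4 gave at least the 9 shifted lists of the real split. The count of lists by that test therefore does not part the groups from other splits. Fry in one direction passed 19 lists and was not run over the other splits.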

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

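Tests of the spike-in range, of a constant added signal, of slide and scan, of the single probes of SO_3096 and of SO_3096 with arrays left out were chosen only after the results were seen; the splits of the arrays and the random lists were set out before theirs.

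The count of changed genes, 2812, was matched by 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, and the highest other split gave 0. The same held for the 955 genes changed at least 2-fold, with 1 of 35 splits and 0 in the highest other. Being the largest of 35 splits is the strongest result that 8 arrays can give here. Every other split mixes the groups, and so puts their difference into the spread within its sets. The 0 there is thus no measure of the counts that chance gives, and the real split also parts the slides. For the 9 shifted lists chance cannot be excluded: 23 of the 35 splits gave as many, and the highest other gave 17.

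The control signal of the brightest spike-in probe, which the comparisons do not use, was 6.27 times as high on the flow arrays as on the non-flow arrays, 55980 ± 3721 (SD, n = 4) against 8922 ± 1188 (SD, n = 4). The difference has an exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 arrays can give. All arrays of a group lay on 1 slide, so they are not independent for a control signal. The p-value therefore does not part condition from slide and scan. Of the 10 spike-in probes 8 were well above background on all arrays, and of these 7 were brighter and 1 dimmer with flow, at ratios from 0.76 to 6.27. The 75th percentile of gene probe signal was 1017 to 1964 on non-flow and 1216 to 1976 on flow arrays. Scaling to the spike-in probes was not among the settings tried, so whether the rises and falls hold on that scale was not tested.

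Dim genes as a class were higher with flow: the median difference was 0.57 log2 in the dimmest quintile and −0.25 in the brightest, and the interquartile range of gene values was 2.65 ± 0.06 (SD, n = 4) on flow and 3.05 ± 0.06 (SD, n = 4) on non-flow arrays. A narrower signal range acting on all probes alike was not seen in the spike-in probes. The SD of the log2 signals of the 8 well above background was larger on every flow array, by at least 0.44. Over all 10 it was larger by at least 0.79, a result seen before the 8 were chosen. The spike-in signals themselves differed unevenly between the groups, at ratios from 0.76 to 6.27, so this does not decide for the gene probes. A constant signal added to every gene probe stays open: 4.74% of the genes of the dimmest quintile lay below its median gain on all 4 flow arrays, between the bounds set for either verdict. Negative control spots averaged 3.14 ± 0.36 (SD, n = 4) on flow and 2.89 ± 0.27 (SD, n = 4) on non-flow arrays (exact permutation p = 0.314). That p-value has the same limit of 1 slide per group. The median gain was 31.4 in scaled signal, so a constant of that size on the control spots as well is argued against. Slide and scan cannot be told apart from condition, since each slide held 1 condition. The difference in flow and cultivation time also stays open, as untested.

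Of the prophage genes 42 of 75 in LambdaSo, 28 of 41 in MuSo1 and 44 of 53 in MuSo2 rose with flow, and 31 of 41 MuSo1 genes, 27 of 53 MuSo2 genes and 25 of 75 LambdaSo genes lie in the dimmest quintile. Each list's median was higher than the general rise of dim genes gave in random lists. It lay at percentile 100 among 10000 random lists of the same size matched on mean signal. The upper limit of their central 95% was 0.43 for LambdaSo, 0.81 for MuSo1 and 0.56 for MuSo2. These lists draw genes singly, while the estimated correlation between members was 0.12, 0.35 and 0.27 in that order. The percentile therefore does not measure chance, and whether the general rise is the whole of it was not decided. With the trend on mean signal removed, the MuSo1 median went from 1.12 (SD of members 1.33) to 0.35 (SD 1.20), and its camera call ended (adjusted p = 0.0969) because the shift shrank. The medians of LambdaSo (from 0.83 to 0.41) and MuSo2 (from 1.29 to 0.83) shrank too and stayed past the camera threshold, although without the trend removed neither passed with an estimated correlation (adjusted p = 0.721 with an estimated correlation for both). Cross-binding between the Mu-like regions was not tested, as the files hold no probe sequences, and slide stays open as above.

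SO_3096, fixed ahead of the data, was higher with flow. A local spot or print fault is argued against, since the smallest difference of any single probe of SO_3096 was 2.77 log2. So is 1 aberrant culture, since at least 98% of the difference was kept with any 1 array left out. The 10 genes with the largest rise were chosen for size and for no overlap, so these tests decide nothing for them. Slide and scan stay open, and so does an effect of flow or of cultivation time, which the design does not part from each other or from slide.

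Among 370 series of 4 values examined, 21 (5.7%) had a replicate standing apart from the other 3, where chance flags about 1 in 20 groups. By gene, the gap to the nearest value as a share of the range was 0.849 for SO_0103 and 0.878 for SO_1337 and 0.92 for SO_1856 (fabA) with flow replicate 4 highest, 0.958 for SO_1724 (pstA) with flow replicate 4 lowest, and 0.965 for SO_0476 with flow replicate 3 lowest. In the non-flow group it was 0.866 for SO_3019 and 0.907 for SO_3252 with replicate 1 highest, 0.844 for SO_1781 and 0.915 for SO_3834 (hemA) with replicate 1 lowest, 0.894 for SO_0704 (groL) with replicate 2 highest, 0.84 for SO_1070 (katB) and 0.904 for SO_2122 with replicate 2 lowest, 0.923 for SO_4751 (atpF) with replicate 3 lowest, 0.904 for SO_1532 with replicate 4 highest and 0.906 for SO_4322 with replicate 4 lowest. For list means in the non-flow group it was 0.849 for heme biosynthesis, 0.865 for hydrogenases and formate dehydrogenases, 0.941 for lactate and pyruvate use and 0.878 for fatty acid biosynthesis with replicate 1 lowest, 0.896 for ribosomal proteins with replicate 3 lowest and 0.873 for biofilm matrix with replicate 4 lowest. Non-flow replicate 1 accounts for 8 of the 21.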

How the results depend on the processing

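Removal of the trend on mean signal was chosen after seeing the data; the other settings were planned. The rise of SO_3096 kept its direction and call under all settings, between 3.33 (median scaling) and 4.01 (brightest probe). The count of changed genes was 1399 (1079 higher, 320 lower) with no scaling and between 2548 and 2848 with an array left out. The count changed at least 2-fold was 631 with normexp before 75th percentile scaling and 557 with normexp and quantile, and 918 to 1011 with an array left out. The number of shifted lists was 5 with the trend removed, 0 with an estimated correlation, 19 with fry in one direction and 33 with fry in either direction, and 9 to 12 with an array left out. The gap between within-group and between-group correlations was 0.0518 to 0.0589 with an array left out. The cause of these shifts was not tested.

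These genes changed sign: with quantile normalization SO_1499 (−0.11) and SO_1781 (−0.06); with cyclic loess SO_1499 (−0.04), SO_1781 (−0.01), SO_0958 (0.13), SO_1070 (0.01) and SO_1158 (0.05); with the trend removed SO_1499 (−0.18), SO_1781 (−0.10), SO_1495 (−0.01), SO_0958 (0.24), SO_1070 (0.10) and SO_1158 (0.14); with the median of the probes SO_0170 (0.01). Genes called neither as reported nor under the setting were not examined for sign. The cause of the sign changes was not tested. With the trend removed the list calls also ended for ATP synthase (adjusted p = 0.0969), aminoacyl-tRNA synthetases (0.360) and pili (0.261).

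Replicate numbers did not pair the arrays: same-numbered deviations correlated between −0.112 and 0.0748 and others up to 0.313, so not every array went best with its own number. With the replicate number as a block 2694 genes changed, 957 at least 2-fold, and 13 lists shifted, and SO_3096 rose by 3.50. Of the named genes' values under the other settings 3281 were counted as unchanged, 153 fell short of the threshold and 1 newly passed. A gene called neither as reported nor under the setting counted as unchanged whatever its sign. Leaving out saturated spots was not run, as 0 spots were saturated, nor was a slide block, as each slide held 1 group. Low signal limits the dimmest genes most. Arrays had a median signal of 9.79 to 19.8 times background.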

Other observations

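The test of thiol and methionine repair genes and the one on megaplasmid genes were set out before their results, on patterns already seen; runs of neighbouring genes were described, and the repair genes tested without ahpF, after seeing the data.

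Some strong changes came in blocks of neighbouring locus tags, which held 189 of the 905 chromosomal genes changed at least 2-fold (20.9%); whether chance gives as many was not tested. In 29 runs at least 4 neighbouring genes all changed at least 2-fold in the same direction, 24 of them higher and 5 lower with flow. From SO_0101 to SO_0109 all 9 genes rose (median log2 2.13), among them fdnG (2.74) and fdhD (3.22), for formate dehydrogenase and its maturation, and selA (2.13) and selB (2.78), for selenocysteine insertion. SO_2007 to SO_2011 rose with a median of 4.32 and SO_3096 to SO_3099 with a median of 3.76, with SO_3097 at 4.01. SO_3556 to SO_3560 rose with a median of 3.47, gshA, for the first enzyme of glutathione synthesis, at 3.47. SO_0950 to SO_0955 included dsbC, for a periplasmic disulfide isomerase, at 3.65. The run SO_2263 to SO_2266, with iscR (−2.09), iscU (−1.58) and iscA (−1.14) of iron-sulfur cluster assembly, fell, and so did SO_4506 to SO_4511 (median −1.86).

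Genes with megaplasmid locus tags were mostly higher with flow: of 160 tested, 102 rose, 16 fell and 42 did not pass the test, with a median of 0.66. This median was higher than the general rise of dim genes gave in 10000 random lists matched on mean signal. It lay at percentile 100, and the median of the random lists was −0.04. These lists draw genes singly, and no correlation between the megaplasmid genes was estimated. The percentile therefore does not measure chance. Plasmid copy number was not measured, and slide stays open here too.

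The rises of msrP, msrQ, gshA and dsbC led to the hypothesis that genes of thiol and methionine repair rise in general. It was tested on 9 other members, of which ahpF had already been counted in the oxidative stress list, and it failed: their median lay at percentile 2.14 of matched lists, toward the low end, and without ahpF, a test chosen after the result was seen, at percentile 1.15. gorA, for glutathione reductase, rose by 2.51, but trxA (−1.14), msrA (−0.92), tpx (−0.74), bcp (−0.65) and trxC (−0.63) fell, gshB (0.48) and dsbB (0.44) rose, and ahpF had −0.21 (limma adjusted p = 0.311).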
